A study of Mus musculus with 6 samples.

How the data were processed

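Skin cells of newborn mice at postnatal day 0 were sorted by flow cytometry, and bulk RNA sequencing was done on 6 libraries, 3 labelled control and 3 labelled Ring1a/b 2KO (knockout of Ring1 and Rnf2, which encode RING1A and RING1B, the ubiquitin ligases of Polycomb repressive complex 1, a chromatin complex that represses genes). Per the labels' protocols, back skin was digested with collagenase and trypsin, and cells were stained for EpCAM, an epithelial surface protein, for Sca1, encoded by Ly6a, and for α6-integrin, encoded by Itga6. The labels call the sorted cells hair follicle cells, while the protocol text attached to the same samples describes a gate for interfollicular epidermis, positive for EpCAM and Sca1 and high in α6-integrin. Which of these gates gave these libraries is not given in the sources used here. Per the labels' protocols, 10 ng of total RNA was reverse transcribed and amplified with the Ovation RNA-seq System V2, libraries were made from 100 ng of sheared cDNA, and single reads of 100 nt were obtained on an Illumina HiSeq. Amplification from so little RNA, without molecular identifiers, adds spread between libraries, and reads that copy the same molecule are not independent, so counting intervals and floors given here cover counting error only.

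The deposited files hold counts: whole numbers of reads per gene, not normalized, 1 file per library, with 24453 gene symbols each. The authors' counts came, per the submitters' processing notes, from a workflow that names TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1, DESeq2 1.6.3 and the genome build mm10; the role of each tool, the gene annotation, the strand setting and any read filter are not given in the sources used here. No row lacked a gene name. Of the rows, 4549 held 0 counts in all 6 libraries. The ribosomal RNA row Rn45s took between 2.35% and 10.3% of a library's counts. Because strand use is not stated, reads of a gene and of a gene overlapping it on the other strand cannot be told apart, as for Foxl2os and Foxl2 or Zic1 and Zic4. Members of families with near-identical copies (Krt6a and Krt6b, the Sprr2, Stfa, Skint and Clca3 genes) may share reads, and their values are uncertain in that respect.

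Total counts per library ranged from 24.8 M to 30.8 M (M, mega), so that 1 count corresponds to between 0.0325 and 0.0404 CPM (counts per megacount). From the deposited counts, genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) with default settings, which left 14972 genes. Libraries were scaled by TMM, with factors given in edgeR's fit, and the groups were compared by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 counted as past the threshold. CPM values are TMM-scaled and are given per library or as mean ± SD with n = 3 libraries per group. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. A fold against a group with 0 counts in all libraries is a lower bound, computed against 3 counts over the group (a floor of 0.0334 CPM in the control group and 0.0371 CPM in the 2KO group). Where a group held 1 to 3 counts in all, the ratio is given with its 95% exact Poisson interval. Gene coordinates are those of GENCODE vM21 (GRCm38, the assembly that mm10 names), in which 97.1% of the rows matched 1 gene by symbol.

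The design, the tests, 27 gene lists and most alternatives were fixed before the data were examined. The lists were targeted genes, other PRC1 subunits, PRC2 subunits, Hox genes, other developmental transcription factors, Merkel cell, hair follicle stem and progenitor, hair germ and follicle signaling, hair matrix with inner root sheath and shaft, basal keratinocyte and hemidesmosome, epidermal differentiation, stress and wound keratinocyte, desmosome and adherens junction, INK4-ARF and CDK inhibitors, S phase, G2 and mitosis, p53 targets, dissociation and immediate early response, sebocyte, dermal fibroblast, melanocyte, endothelial, immune, skeletal muscle, Schwann and nerve, red blood cell, and sex-linked genes. For each list the members past the threshold were counted. Each of the 25 lists with at least 5 tested members was compared with all other tested genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Each was also tested with fry, which tests the list's genes against no change and does not compare them with other genes. The fry values given are those for a shift of the list in a shared direction, unless the mixed test, for change in either direction, is named. The rule for named genes was also fixed. It took Ring1, Rnf2, Epcam, Ly6a, Itga6 and Krt14. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 2 CPM, no overlap between the groups and a symbol that is not a predicted one. It took up to 4 members per list with the smallest p among those past the threshold, or, where none passed, up to 2 with the highest mean CPM, which could also be given for a list of at least 10 members with fewer than 3 calls. Some genes that this rule names are not reported here. Other genes named here were chosen after their values were seen. These are further list members, called or not, and, in the closing observations, the imprinted, Skint, Clca and fibroblast genes.

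Alternatives fixed beforehand were size factors of DESeq2 in the same fit, library size alone, no low-count filter, a filter of over 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, log2 CPM of Xist as a covariate, each library left out in turn, an adjusted p under 0.01 and a minimum of 2-fold. Chosen after the data were seen were the removal of both replicate-3 libraries, of both replicate-1 libraries and of Rn45s, and offsets that remove trends of counts with transcript GC content and length (lowess with a span of 0.3). The fit was tested on simulated counts for 14661 genes in 3 libraries against 3, with 200 changed genes. It recovered 11.0% of 100 genes changed 2-fold and 69.0% of 100 genes changed 4-fold, and 8.0% of its calls were unchanged genes. Changes of 2-fold or less were thus often missed in the simulation. The adjusted threshold is stricter where fewer genes change, so the share missed in the real comparison, with its 1351 calls, may be smaller. In the same simulation camera called the 1 changed list and 0 of 100 unchanged lists. Each gene was drawn independently there, so the simulation cannot test camera on lists whose genes vary together. In the real lists the estimated correlation reached 0.83 (G2 and mitosis). Every pair of libraries of a group differed by far more than counting noise (chi-square per degree of freedom from 67.2 to 160.9), so none was a copy of another. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. Python 3.11.15 with numpy, pandas, scipy and matplotlib was used for tables and figures.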

Results

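Gene expression was measured by RNA sequencing in sorted skin cells of newborn mice, in 3 libraries labelled control and 3 labelled Ring1a/b 2KO. The series concerns the role of Polycomb repressive complex 1 in the development of skin epithelium, and its single comparison asks which genes differ when both RING1 proteins, the catalytic subunits of the complex, are lost. The libraries labelled control held 28.2, 30.4 and 30.8 M counts (M, mega) and those labelled 2KO held 26.7, 29.9 and 24.8 M. Between 16591 and 17817 genes were detected per library. Spearman correlations between libraries ranged from 0.968 to 0.972 within the control group, from 0.954 to 0.966 within the 2KO group and from 0.935 to 0.954 between the groups. The first principal component of log2 CPM held 54.0% of the variance and separated the groups, with the libraries labelled control between -80.9 and -57.7 and those labelled 2KO between 67.8 and 76.4. The second held 17.1% and set control replicate 1 (44.8) and 2KO replicate 1 (68.5) apart from the other 4 libraries, which lay between -32.9 and -23.8.

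The targeted genes did not separate the groups. Ring1 (RING1A, chromosome 17, 34020792 to 34024680, minus strand) was at 19.5, 22.4 and 3.37 CPM in the libraries labelled control and at 1.84, 7.34 and 14.1 CPM in those labelled 2KO. Rnf2 (RING1B, chromosome 1, 151458004 to 151500955, minus strand) was at 67.7, 79.5 and 47.1 CPM in the libraries labelled control and at 75.3, 66.4 and 89.2 CPM in those labelled 2KO. The log2 fold change of 2KO against control was -0.96 (SE 0.76, edgeR adjusted p = 0.537) for Ring1 and 0.25 (SE 0.23, edgeR adjusted p = 0.615) for Rnf2. With Xist as a covariate the value for Ring1 turned to 0.04, and with both replicate-3 libraries left out that for Rnf2 turned to -0.05, both still short of the threshold. Ring1 thus went against the label of control replicate 3, and Rnf2 was not lower in any library labelled 2KO than in control replicate 3. The labels do not say which part of either gene the knockout removes, and counts over a whole gene check nothing where the remaining part is still transcribed. For this reason the groups are called by their labels throughout, and each direction below is one between libraries so labelled.

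Of the genes of the sort, Epcam was at 195 ± 51.8 CPM in the libraries labelled control and 282 ± 65.7 in those labelled 2KO (edgeR adjusted p = 0.223), Itga6 at 782 ± 97.1 and 973 ± 108 (adjusted p = 0.342), and Krt14, a keratin of basal keratinocytes, at 2660 ± 1310 and 3560 ± 635 (adjusted p = 0.541). Ly6a, which encodes the Sca1 antigen, was low in all 6 libraries, between 1.92 and 7.28 CPM, and did not differ between the groups by the test (adjusted p = 0.932).

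**Figure D1:**
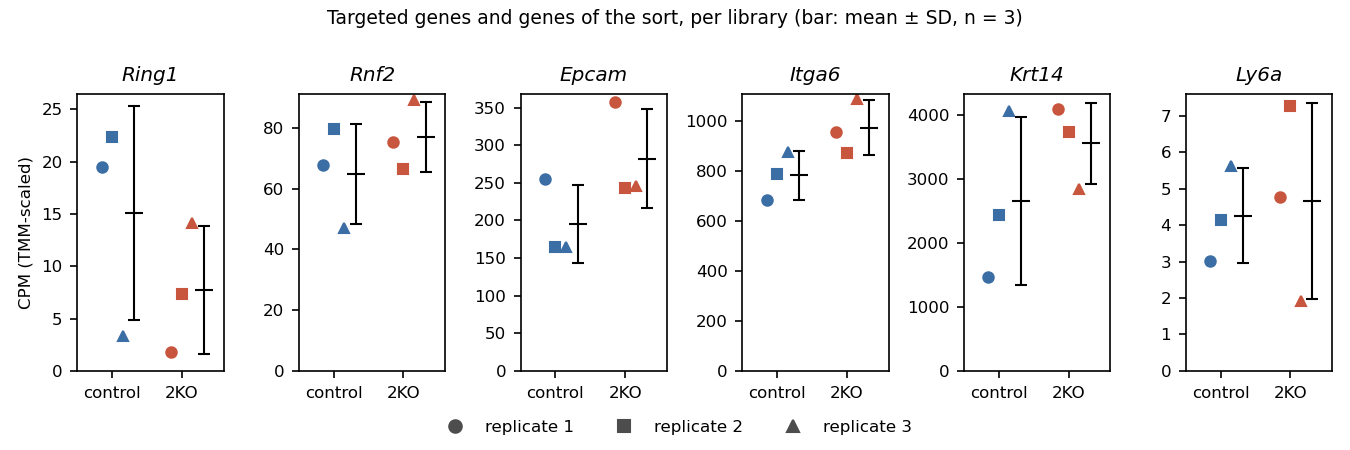
TMM-scaled CPM of the targeted genes Ring1 and Rnf2 and of the genes of the sort in each library, with a symbol per replicate number and the mean ± SD (n = 3) beside each group. Ring1 in control replicate 3 (3.37 CPM) lies below 2KO replicates 2 and 3 (7.34 and 14.1 CPM), and Ly6a stays below 7.28 CPM or at that value in all 6 libraries.

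Between the libraries labelled 2KO and those labelled control, 1351 of 14972 tested genes passed the threshold, 989 higher and 362 lower in 2KO (edgeR quasi-likelihood test). Genes that were almost silent in the libraries labelled control made up 307 of those that rose (31.0%, control mean under 1 CPM), and 42 of them had 0 counts in all 3 control libraries. Of the genes that fell, 59 (16.3%) had a mean under 1 CPM in the libraries labelled 2KO. The groups did not overlap for 28.4% of the tested genes, where chance gives 10%. The number of higher genes was 615 without control replicate 3. The number of lower genes was 198, 236 and 190 without control replicates 1, 2 and 3, 184 and 222 without 2KO replicates 2 and 3, 228 with Xist as a covariate and 733 with DESeq2. With both replicate-3 libraries left out, 309 genes were higher and 72 lower, and 47 of 94 named genes kept their call.

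Among the 10 largest rises by the fixed rule were those of Dmrt3, Sim2, Wt1, Nell2, Sall1, Barx1, Foxl2os and Dmrt1. Of these 8, 6 encode transcription factors of development, Nell2 encodes a secreted protein of neural tissue, and Foxl2os is a noncoding RNA that overlaps Foxl2 on the other strand. Sim2 (chromosome 16, 94084931 to 94127032), a factor of midline development, was at 39.1, 44.4 and 48.1 CPM in the libraries labelled 2KO. It had 1 count over the 3 libraries labelled control, a ratio of 3940 (95% counting interval 706 to 155000, edgeR adjusted p = 2.59e-05). Barx1, a homeobox gene of stomach and tooth development, reached 37.8 ± 5.84 CPM against 2 counts over the libraries labelled control, a ratio of 1690 (95% counting interval 469 to 14000). Dmrt3 and its neighbour Dmrt1 on chromosome 19, related factors of sex determination and neural development, were at 14.8 ± 3.52 and 5.0 ± 1.94 CPM in 2KO and at 0 counts in every library labelled control, so that they were at least 443-fold and 149-fold higher. Wt1 (11.9 ± 5.40 CPM), a factor of kidney and gonad development, was at least 354-fold higher.

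The largest falls were those of Krt25, Cyp2g1, Fa2h, Krt28, Skint9, Kcnj16, Hsd3b6, Cps1, Gadl1 and Cyp2f2. Krt25 and Krt28 (chromosome 11, 99315516 to 99322951 and 99364872 to 99374903) encode keratins of the inner root sheath, the layer that surrounds the growing hair. Krt25 was at 25.8, 10.6 and 18.7 CPM in the libraries labelled control and at 0 counts in all 3 labelled 2KO, at least 495-fold lower, and Krt28 fell from 21.7 ± 5.06 CPM to 1 count over 3 libraries (ratio 1760, 95% counting interval 316 to 69500). Fa2h, which encodes fatty acid 2-hydroxylase, an enzyme of skin lipids, was at 6.06 ± 1.31 CPM and at 0, at least 163-fold lower. Gadl1, which encodes a decarboxylase, fell from 33.8 ± 19.6 to 0.340 ± 0.402 CPM (log2 fold change -6.66, SE 0.91, edgeR adjusted p = 0.00249), but missed the threshold with both replicate-3 libraries left out (adjusted p = 0.0637).

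**Figure D2:**
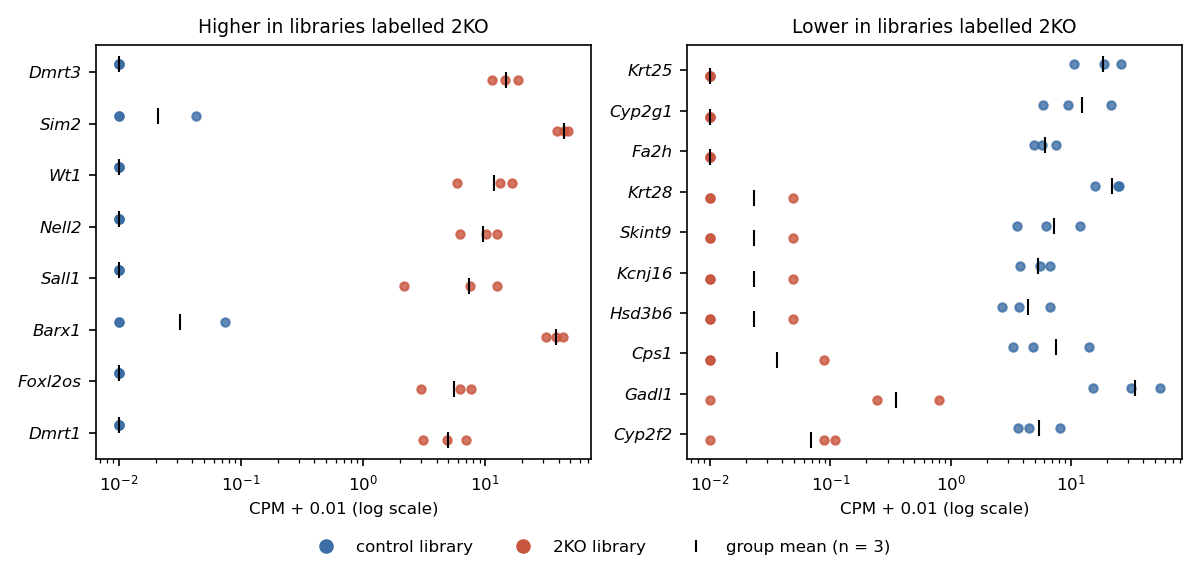
CPM + 0.01 on a log scale for 8 of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) between libraries labelled 2KO and libraries labelled control. Each point is a library and each black tick a group mean (n = 3); points at 0.01 are libraries with 0 counts, as for Dmrt3 in the control group and Krt25 in the 2KO group.

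Transcription factors of other lineages formed the group with the most rises. Of 70 tested members of the list of other developmental transcription factors, 49 rose in the libraries labelled 2KO, 2 fell (Dlx2 and Irx2) and 19 did not pass, and 57 and 2 passed when adjusted over the list alone. A further 54 members had too few counts to be tested. A member silent in the libraries labelled control could be tested only if it was high in 2KO, which tilts the tested members and their median toward rises. With no low-count filter 52 members rose. Gata4, a factor of heart and endoderm, was at 21.4 ± 3.17 CPM against 0.0453 ± 0.0222 (log2 fold change 8.77, SE 0.46, edgeR adjusted p = 3.5e-05), Zic1, a factor of neural development, at 48.5 ± 6.31 against 0.0464 ± 0.0545, and Pax3, a factor of muscle and neural crest, at 23.9 ± 7.01 against 0.444 ± 0.0506. The median fitted log2 fold change was 5.54, and 5.04 with 11 members that had 0 counts in a group set to their bound. The list stood above all other tested genes (camera adjusted p = 2.56e-62), also with no low-count filter (adjusted p = 3.89e-42) and with an estimated correlation (adjusted p = 0.00773). The number of risen members was 25 with both replicate-3 libraries left out, a comparison of 2 libraries against 2 in which high Xist follows the group label. The 2 falls shrank to 1 without 2KO replicates 1 or 3 and to 0 without any other library. In the same libraries 8 of 24 tested dermal fibroblast genes, described below, rose (camera adjusted p = 0.000305 for the list, and adjusted p = 0.284 with an estimated correlation).

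Hox genes, which specify position along the body, moved both ways. Of 36 tested, 8 rose in the libraries labelled 2KO (Hoxa9, Hoxa10, Hoxa11, Hoxa13, Hoxb13, Hoxc10, Hoxc11 and Hoxd13), 2 fell (Hoxa2 and Hoxc13) and 26 did not pass, and 12 and 5 passed when adjusted over the list alone. Hoxd13 (chromosome 2, 74668310 to 74671599) reached 30.1 ± 6.93 CPM against 0.0647 ± 0.0853, Hoxa13 10.0 ± 3.14 against 0.0861 ± 0.149, and Hoxa10 7.27 ± 2.53 against 0.309 ± 0.187. Hoxc13, a gene expressed in hair, fell from 41.1 to 19.3 CPM (edgeR adjusted p = 0.0274). The list's median log2 fold change was -0.10 and its mean 1.40, while camera placed it above other genes (adjusted p = 0.0387). For a shift in 1 direction fry did not pass (adjusted p = 0.156), while its mixed test, for change in either direction, did (adjusted p = 0.000163). The camera call was lost with an estimated correlation (adjusted p = 0.676), with the CPM filter (0.0666) and with limma-voom (0.244). It was also lost with both replicate-3 libraries left out (0.138), and without control replicate 1 (0.11), 2KO replicate 2 (0.132) or 2KO replicate 3 (0.147). In each of these last 3 fits 5 Hox genes rose. The number of fallen Hox genes was 0 without 2KO replicate 2 and 1 without control replicates 2 or 3 or 2KO replicate 1.

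**Figure D3:**
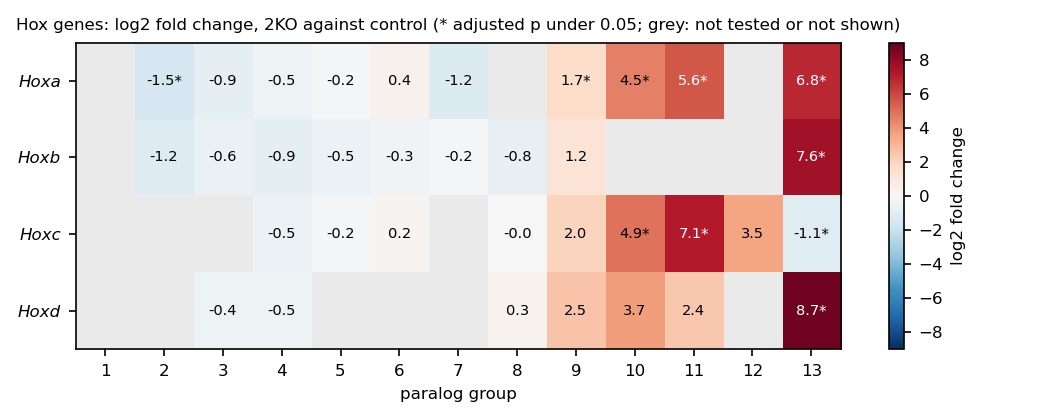
Fitted log2 fold change of tested Hox genes, libraries labelled 2KO against libraries labelled control, by cluster (rows) and paralog group (columns); an asterisk marks an edgeR adjusted p under 0.05 and grey a gene not tested, not existing or not shown. The highest value is 8.73 (Hoxd13), and of the starred genes Hoxa2 and Hoxc13 are lower.

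Among subunits of the Polycomb complexes, 4 of 26 tested members of the list of other PRC1 subunits rose in the libraries labelled 2KO and none fell; 4 rose when adjusted over the list alone. Phc1, a subunit of canonical PRC1, went from 49.6 ± 6.48 to 101 ± 8.65 CPM (log2 fold change 1.03, SE 0.18, edgeR adjusted p = 0.00871), Cbx6, a chromodomain subunit, from 48.3 ± 0.361 to 92.6 ± 15.7, and Bcorl1 and Bcor, related corepressors on the X chromosome, from 25.9 ± 0.942 to 52.0 ± 3.63 and from 138 ± 12.2 to 215 ± 6.12. The call of Bcor was lost whichever library was left out (adjusted p = 0.0736, 0.0696 and 0.147 without control replicates 1, 2 and 3, and 0.0567, 0.0906 and 0.0533 without 2KO replicates 1, 2 and 3). That of Cbx6 was lost without control replicates 2 (0.0511) and 3 (0.0604) and 2KO replicate 2 (0.0575), so that 2 subunits rose in each of these fits. With both replicate-3 libraries left out none passed, with an edgeR adjusted p of 0.113 for Phc1 and 0.0742 for Bcorl1. The list did not differ from other genes (camera adjusted p = 0.259), while fry, which tests it against no change, passed (adjusted p = 0.0339). Of 12 PRC2 subunits none passed the threshold over all genes, and 1 rose and 2 fell when adjusted over the list alone. Without 2KO replicate 3, 1 rose. The most abundant members were Jarid2, at 175 ± 34.0 and 246 ± 43.2 CPM, and Aebp2, at 166 ± 6.62 and 213 ± 18.4 (edgeR adjusted p = 0.186 and 0.204). Of the 12 members 4 had a fold change above 0 and 8 below (list median -0.14, camera adjusted p = 0.652). Ezh2 was at a mean of 119 CPM in the libraries labelled control and 77.7 in those labelled 2KO (edgeR adjusted p = 0.0607). With DESeq2 1 member rose and 2 fell, Ezh2 among these (adjusted p = 0.0294).

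Of 29 tested members of the list of hair matrix, inner root sheath and shaft genes, 11 fell in the libraries labelled 2KO and none rose (14 and 1 when adjusted over the list alone). The 11 include the inner root sheath keratins Krt25, Krt26, Krt27, Krt28, Krt71 and Krt73, the hair keratin Krt35, the hair desmosome gene Dsg4, Lap3, and Dlx3 and Msx2, transcription factors of hair differentiation. Krt71 fell from 15.6 ± 4.93 to 0.271 ± 0.224 CPM (log2 fold change -5.85, SE 0.63, edgeR adjusted p = 0.001) and Krt35 from 13.1 ± 2.16 to 0.694 ± 0.471 (log2 fold change -4.24, SE 0.58, adjusted p = 0.00251). The median of the list was -1.04, and the list stood below other genes (camera adjusted p = 4.58e-13, and 0.0166 with an estimated correlation). The number of fallen members was 7 with both replicate-3 libraries left out.

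Genes of follicle progenitors and of follicle signaling changed in both directions. Of 30 tested stem and progenitor genes, 6 fell and 2 rose in the libraries labelled 2KO (8 and 4 when adjusted over the list alone). Lrig1, a marker of upper follicle stem cells, fell from 212 ± 37.2 to 87.4 ± 13.6 CPM (log2 fold change -1.28, SE 0.19, edgeR adjusted p = 0.00399), and Vdr, the vitamin D receptor, from 209 ± 9.43 to 74.2 ± 28.0. Nfatc2 rose from 2.16 ± 0.65 to 26.7 ± 15.5 CPM and Aldh1a3, an enzyme of retinoic acid synthesis, from 1.72 ± 0.709 to 10.3 ± 3.04. The list missed the threshold as a set (camera adjusted p = 0.0608), and passed it without control replicate 2 (0.0165), control replicate 3 (0.0104) or 2KO replicate 1 (0.00231). It also passed with no low-count filter (0.0238), with GC and length offsets (0.0207) and with both replicate-1 libraries left out (0.0126). The camera threshold was missed with an estimated correlation (adjusted p = 0.676) and with Xist as a covariate (0.136). It was also missed without control replicate 1 (0.263) and without 2KO replicates 2 (0.0894) or 3 (0.147). Of 42 hair germ and signaling genes, 1 fell and 3 rose, also when adjusted over the list alone. Shh, a ligand made by the growing follicle, fell from 117, 66.0 and 80.5 CPM to 36.3, 18.9 and 13.3 (log2 fold change -1.94, SE 0.38, adjusted p = 0.012). The rises were those of the receptor Notch1 (686 ± 54.3 to 1310 ± 251) and the ligands Bmp4 (40.9 ± 5.15 to 85.2 ± 19.8) and Bmp7 (361 ± 23.6 to 647 ± 141). The call of Shh was lost without 2KO replicate 2 (adjusted p = 0.0512), that of Notch1 without control replicate 2 (0.0611) and 2KO replicate 2 (0.0555), and that of Bmp4 without control replicate 3 (0.0763). Bmp7 lost its call without control replicates 1 (0.0609), 2 (0.0963) and 3 (0.0698) and 2KO replicates 2 (0.0847) and 3 (0.0756). The number of risen signaling genes was 1 without control replicates 2 or 3 or 2KO replicate 2, and the number of fallen ones 0 without 2KO replicate 2 and 2 without 2KO replicate 3. The list did not differ from other genes (camera adjusted p = 0.627).

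In the list of epidermal differentiation genes, 5 of 58 tested members rose in the libraries labelled 2KO and 3 fell (8 and 4 when adjusted over the list alone), and the set did not differ from other genes (camera adjusted p = 0.729). The number of risen members was 2, 3 and 2 without control replicates 1, 2 and 3, and 10 and 1 without 2KO replicates 1 and 2, and 5 fell without control replicate 1. The set passed the threshold without 2KO replicate 1 (0.00487), which with control replicate 1 had the lowest mean level of the list. In the fit of all libraries its estimated correlation was 0.59, at which the camera adjusted p was 0.938. The direction of the set turned without control replicate 1 and without 2KO replicate 2. Sprr1a, a precursor of the cornified envelope, rose from 129 ± 55.6 to 872 ± 479 CPM (log2 fold change 2.76, SE 0.46, edgeR adjusted p = 0.00622). Krt77, a suprabasal keratin, fell from 25.2 ± 15.8 to 1.80 ± 0.930 CPM, Tgm3, an epidermal transglutaminase, from 33.4 ± 15.8 to 7.17 ± 1.37, and Skint4 from 9.45 ± 3.27 to 1.13 ± 0.626. Krt1 (4670 ± 2610 and 1470 ± 821 CPM) and Krt10 (2750 ± 1480 and 698 ± 421) did not pass (edgeR adjusted p = 0.101 and 0.0598). They passed as lower in 5 and 6 of 18 alternatives, DESeq2 among them. Of the list, 37 members lay above 0 and 21 below. In the stress and wound list 3 of 27 tested genes rose and 2 fell (8 and 3 when adjusted over the list alone, camera adjusted p = 0.218). Krt6a, a keratin of wounded epidermis and of the follicle's companion layer, rose from 3.48, 41.1 and 37.6 CPM to 887, 1090 and 584 (log2 fold change 4.96, SE 0.76, adjusted p = 0.0043). Defb4, a defensin, was at 1.07 ± 0.928 CPM and at 0 in every library labelled control, at least 31-fold higher, and Stfa3, a cystatin, fell from 481 ± 283 to 50.6 ± 32.7 CPM. The calls of Krt77, Tgm3, Krt6a and Stfa3 were lost with both replicate-3 libraries left out, and that of Defb4 without control replicates 1 (0.0638), 2 (0.0608) and 3 (0.0726) and 2KO replicate 2 (0.0945). The number of risen stress genes was 1 without control replicate 3 or 2KO replicate 2 and 6 without 2KO replicate 1, and 1 fell without any library but control replicate 1.

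Of 22 tested genes of desmosomes and adherens junctions, 5 rose in the libraries labelled 2KO (Pkp2, Dsg3, Dsg2, Pkp4 and Ctnnb1) and none fell, also when adjusted over the list alone. Pkp2, a plakophilin of simple epithelia and heart, rose from 2.50 ± 1.58 to 25.8 ± 6.21 CPM (log2 fold change 3.36, SE 0.53, edgeR adjusted p = 0.00475), Dsg3 from 326 ± 44.5 to 638 ± 44.1 and Dsg2 from 253 ± 37.4 to 504 ± 71.5. The camera adjusted p of 0.0029 rose to an adjusted p of 0.284 with an estimated correlation. Without control replicate 2, 3 genes passed, and Pkp4 did not (adjusted p = 0.058). Without 2KO replicate 3, 2 basal genes rose. Of 30 tested basal keratinocyte and hemidesmosome genes, 1 rose, also when adjusted over the list alone (Igfbp2, an insulin-like growth factor binding protein, 37.6 ± 18.7 to 277 ± 99.3 CPM, adjusted p = 0.00241), and the set did not differ from other genes (camera adjusted p = 0.92). The abundant basal genes Krt5 (11500 ± 4320 and 15700 ± 3670 CPM) and Dst (5100 ± 1310 and 5640 ± 1730 CPM) did not pass (edgeR adjusted p = 0.453 and 0.833).

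**Figure D4:**
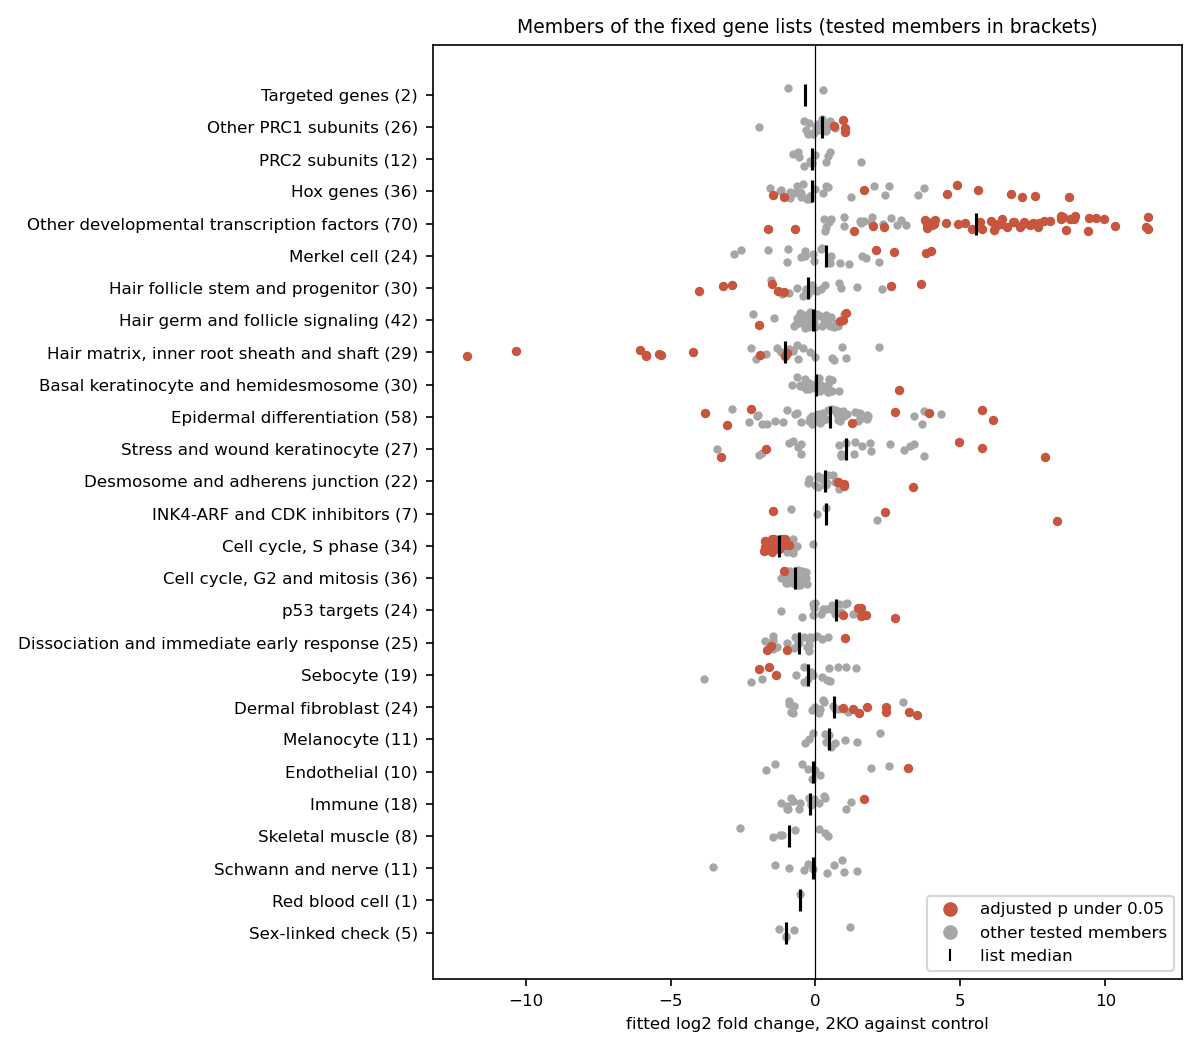
Fitted log2 fold change of each tested member of the 27 fixed lists, libraries labelled 2KO against libraries labelled control, with members past an edgeR adjusted p of 0.05 in red, other members in grey and the list median as a black tick. The median lies at 5.54 for other developmental transcription factors, at -1.27 for S phase and at -1.04 for hair matrix, inner root sheath and shaft; values of genes with 0 counts in a group depend on the prior count.

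All 34 tested S phase genes had a fold change below 0 and 22 passed the threshold, all lower in the libraries labelled 2KO (31 when adjusted over the list alone), with a median of -1.27. Among the subunits of the replicative helicase, Mcm6 fell from 136 ± 37.5 to 41.0 ± 5.97 CPM (log2 fold change -1.73, SE 0.24, edgeR adjusted p = 0.0027), Mcm2 from 101 ± 8.37 to 34.4 ± 10.2 and Mcm4 from 162 ± 24.5 to 68.2 ± 12.5, and the chromatin remodeler Hells fell from 50.3 ± 1.73 to 19.3 ± 3.35. Of 36 tested genes of G2 and mitosis, all had a fold change below 0 (median -0.69) and 1 passed, Ccna2 (85.3 ± 27.6 to 39.9 ± 9.51 CPM, adjusted p = 0.0379); none passed when adjusted over the list alone. Mki67 was at 2010, 714 and 931 CPM in the libraries labelled control and at 764, 489 and 490 in those labelled 2KO (adjusted p = 0.113). Both sets stood below other genes (camera adjusted p = 7.47e-20 and 1.97e-05), which did not hold with an estimated correlation (adjusted p = 0.284 and 0.676). Against no change, fry passed for S phase (adjusted p = 0.0262) and not for mitosis (adjusted p = 0.373). The number of fallen S phase genes was 7 without control replicate 1, 12 without control replicate 3, 12 without 2KO replicate 2, 8 without 2KO replicate 3, 3 without both replicate-3 libraries, and 13 with Xist as a covariate. The call of Ccna2 was lost without control replicates 1 (0.129) and 3 (0.0816) and 2KO replicates 2 (0.113) and 3 (0.12), and 3 mitosis genes fell without control replicate 2. With the replicate number as a block 8 mitosis genes fell, Mki67 and Top2a among them.

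Among 7 inhibitors of cyclin-dependent kinases, Cdkn1c and Cdkn2a rose and Cdkn1b fell in the libraries labelled 2KO (3 and 1 when adjusted over the list alone, camera adjusted p = 0.218). Against no change, fry passed for this list (adjusted p = 0.027). Cdkn1c, an imprinted gene that encodes p57, rose from 15.3 ± 6.20 to 80.9 ± 23.1 CPM (log2 fold change 2.40, SE 0.34, edgeR adjusted p = 0.00271). Cdkn2a, the INK4-ARF gene, was at 2.55, 0.567 and 1.14 CPM and at 0 counts in every library labelled control, at least 42-fold higher, and its call was lost without 2KO replicate 1 (adjusted p = 0.0541). Of 24 tested p53 targets, 6 rose and none fell (9 and 1 when adjusted over the list alone). Ccng1 rose from 81.3 ± 6.22 to 243 ± 32.2 CPM (log2 fold change 1.58, SE 0.17, adjusted p = 0.001), Zmat3 from 162 ± 16.4 to 540 ± 168 and Polk, a translesion polymerase, from 33.3 ± 4.24 to 91.2 ± 33.2. The set stood above other genes (camera adjusted p = 0.00043), which did not hold with an estimated correlation (adjusted p = 0.105), and 3 genes rose without control replicate 1 or without 2KO replicate 2. With both replicate-3 libraries left out 1 rose, and Zmat3 (edgeR adjusted p = 0.0599) and Polk (0.113) lost their calls.

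Of 24 tested genes of Merkel cells, touch-sensing cells of the skin epithelium, 4 rose in the libraries labelled 2KO and none fell (6 and 0 when adjusted over the list alone). The mechanosensitive channel gene Piezo2 rose from 9.87 ± 1.46 to 42.3 ± 2.51 CPM (log2 fold change 2.10, SE 0.23, edgeR adjusted p = 0.001), Prox1 from 9.23 ± 6.30 to 60.7 ± 9.08 and Krt18 from 1.67 ± 1.27 to 23.9 ± 18.9. Other Merkel cell keratins did not pass: Krt8 was at 1.55 ± 0.350 and 0.786 ± 0.792 CPM and Krt20 at 2.06 ± 0.769 and 0.349 ± 0.252. Krt20 passed as lower with DESeq2 (adjusted p = 0.0354). Atoh1, a member with too few counts to be tested, was at 1.53 ± 1.72 CPM in the libraries labelled control and 0.0654 ± 0.113 in those labelled 2KO. Sox2 (0.905 ± 0.393 and 2.04 ± 1.28 CPM) and Isl1 (2.40 ± 0.581 and 1.69 ± 0.478) did not pass. The set missed the threshold (camera adjusted p = 0.176), passing it without control replicate 2 (0.0474). Of 19 sebocyte genes, 3 fell (Prdm1, 80.3 ± 25.7 to 20.6 ± 7.02 CPM, adjusted p = 0.00613, Far2 and Mgst1) and none rose (4 and 0 when adjusted over the list alone, camera adjusted p = 0.0951, and 0.0379 with no low-count filter). Against no change, fry passed for the sebocyte list (adjusted p = 0.00187). The number of fallen sebocyte genes was 1 without control replicates 1 or 3 or 2KO replicates 1 or 3. Far2 lost its call in these fits (0.0714, 0.0951, 0.0545 and 0.067), as did Mgst1 (0.128, 0.0675, 0.0527 and 0.0701), and Mgst1 also without 2KO replicate 2 (0.103).

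Of 24 tested fibroblast genes, 8 rose in the libraries labelled 2KO and none fell (9 and 1 when adjusted over the list alone). Dlk1 rose from 1.88 ± 0.305 to 17.6 ± 5.92 CPM, Pdgfra from 0.896 ± 0.315 to 10.2 ± 5.23, Fbn1 from 18.4 ± 8.55 to 99.7 ± 37.2 and Col5a1 from 83.8 ± 12.2 to 207 ± 6.84 (edgeR adjusted p from 0.00131 to 0.00405). The collagen genes Col5a2 and Col6a1 were also among the 8. The collagen genes Col1a1 (52.2 ± 29.8 and 83.0 ± 3.15 CPM), Col1a2 (58.2 ± 22.7 and 53.3 ± 16.5) and Col3a1 (61.7 ± 37.4 and 66.5 ± 3.58) did not pass. The list stood above other genes (camera adjusted p = 0.000305), which did not hold with an estimated correlation (adjusted p = 0.284). In the endothelial list 1 of 10 genes rose (Flt1, 0.894 ± 0.769 to 8.11 ± 2.44 CPM, adjusted p = 0.029), with 3 when adjusted over the list alone, and in the immune list 1 of 18 (H2-Ab1, 4.56 ± 0.233 to 14.6 ± 4.21 CPM, adjusted p = 0.0127), also when adjusted over the list alone (camera adjusted p = 0.652 and 0.627). The median of the endothelial list was -0.08 and its mean 0.38. Flt1 lost its call without control replicate 1 (0.0791) and without 2KO replicates 1 (0.0701), 2 (0.0622) and 3 (0.0595). None passed of 11 melanocyte, 8 skeletal muscle and 11 Schwann and nerve genes, over all genes or adjusted over the list alone (camera adjusted p = 0.686, 0.315 and 0.686). The most abundant of these were Trpm1 (49.4 ± 4.63 and 46.1 ± 13 CPM), Mybpc1 (8.25 ± 4.40 and 11 ± 1.68) and Erbb3 (122 ± 9.79 and 103 ± 14.9). The single tested red blood cell gene, Alas2, was at 5.77 ± 1.06 and 4.01 ± 1.18 CPM (adjusted p = 0.529).

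Of 25 tested immediate early and dissociation genes, Zfp36, Fos and Jun fell in the libraries labelled 2KO and Hspb1 rose (4 and 1 when adjusted over the list alone). Fos was at 756, 429 and 446 CPM in the libraries labelled control and at 282, 307 and 245 in those labelled 2KO (log2 fold change -0.97, SE 0.24, edgeR adjusted p = 0.0324). Control replicate 1 held the highest mean level of this list and of both cell cycle lists. The set's camera adjusted p of 0.00475 became an adjusted p of 0.676 with an estimated correlation, 0.194 without control replicate 1 and 0.0948 without 2KO replicate 3. Against no change, fry did not pass (adjusted p = 0.45). The number of fallen genes was 1 without control replicate 1, 6 without 2KO replicate 1 and 0 without 2KO replicates 2 or 3. It was 12 with the replicate number as a block and 7 with both replicate-1 libraries left out. Hspb1 lost its call without control replicates 2 (0.0785) and 3 (0.0974) and 2KO replicates 1 (0.0551) and 2 (0.0834), and Fos without control replicate 1 (0.0751) and 2KO replicates 1 (0.0749), 2 (0.0743) and 3 (0.119). Jun lost its call without control replicate 1 (0.0958) and 2KO replicates 2 (0.11) and 3 (0.0955), and Zfp36 without 2KO replicates 2 (0.0962) and 3 (0.118). The sex-linked genes showed that the groups were not matched for sex. Xist, the RNA of the inactive X chromosome, was at 2.48, 9.27 and 4550 CPM in the libraries labelled control and at 5360, 4950 and 10.4 in those labelled 2KO. Ddx3y on the Y chromosome was at 113, 126 and 0.0327 CPM and at 0.0392, 0.0334 and 119. None of the 5 sex-linked genes passed the threshold between the groups, over all genes or adjusted over the list alone (camera adjusted p = 0.627), and without control replicate 3 Xist did (1 gene higher).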

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

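The fits without both libraries of a replicate number, without Rn45s and with GC and length offsets were chosen after the data were seen. The 989 higher genes became 424 at an adjusted p under 0.01, 309 with both replicate-3 libraries left out and between 615 and 854 with 1 library left out. The 362 lower genes became 733 with DESeq2, 228 with Xist as a covariate, 90 at an adjusted p under 0.01, 72 with both replicate-3 libraries left out and between 184 and 347 with 1 library left out. The 160 calls among list members became 58 with both replicate-3 libraries left out, and the 9 lists past the camera threshold became 2 with an estimated correlation. Fewer libraries lower the power of a fit, and leaving out the replicate-3 libraries also leaves control libraries low in Xist against 2KO libraries high in it; the cause of the other shifts was not tested. Both counts stayed within 1.5 times the reported ones under the other scalings and filters, limma-voom, a minimum of 2-fold, GC and length offsets, without Rn45s and without both replicate-1 libraries. No gene called in the reported fit was called in the opposite direction in any fit. Scalings moved the median of all genes from -0.016 to at most -0.026. Ring1 and Rnf2 passed the threshold in no fit, with Ring1 between -2.18 and 0.04 and Rnf2 between -0.05 and 0.46.

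The replicate numbers did not pair the libraries throughout. Deviations from the group means correlated at 0.29, 0.09 and -0.08 for replicates 1, 2 and 3, and only the replicate-1 libraries correlated best with their own number. The replicate-1 libraries also stood apart on the second principal component, so a factor that they share is not excluded. With the replicate block, 1142 genes were higher and 540 lower, and the stem and progenitor list passed the camera threshold (adjusted p = 0.0148). Fallen G2 and mitosis genes then numbered 8 instead of 1, and fallen immediate early and dissociation genes 12 instead of 3. Over the named genes past the threshold, 1038 of 1123 values from alternatives other than single left-out libraries kept their call, 85 lost it and none turned; with 1 library left out, 490 of 564 kept it. Of the 85 losses 47 came from the removal of both replicate-3 libraries. Depth limits genes near 1 CPM, for which a library holds about 25 to 31 counts.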

Other observations

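Except for the test of GC content and length, that of control replicate 1, that of the spread at Ring1's expression level and the count of splits, the tests below were chosen after the result they bear on was seen. The gene groups of the first 2 paragraphs were picked from their values.

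Several imprinted genes of the Dlk1-Meg3 domain on chromosome 12, picked from their values and not tested as a group, rose in the libraries labelled 2KO. Meg3, a noncoding RNA (109541001 to 109571726), was at 11.1, 10.3 and 4.22 CPM in the libraries labelled control and at 363, 259 and 270 in those labelled 2KO (log2 fold change 5.12, SE 0.38, edgeR adjusted p = 0.000179). Rian went from 3.05 ± 1.15 to 59.3 ± 21.8 CPM and the paternally expressed Rtl1 from 0.211 ± 0.210 to 13.3 ± 4.70, beside the Dlk1 rise given above. Rtl1 overlaps microRNA genes on the other strand, so its value may hold reads of the antisense transcript. Mirg rose (adjusted p = 0.018) but lost its call in 6 of 17 alternatives, among them those without control replicates 2 (0.0676) and 3 (0.0595) and 2KO replicate 2 (0.0653), and Dio3 had too few counts to be tested. Outside this domain the imprinted genes Igf2 (651 ± 330 to 2060 ± 657 CPM, adjusted p = 0.0312) and Grb10 (50.1 ± 37.0 to 233 ± 64.5, adjusted p = 0.0153) rose, while H19 (adjusted p = 0.536) and Peg3 (adjusted p = 0.953) did not pass. Igf2 lost its call without control replicate 2 (0.066) and 2KO replicates 2 (0.0976) and 3 (0.0797), and Grb10 without control replicate 3 (0.0508).

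Skint genes, a chromosome 4 family expressed in skin and thymus epithelium, were lower. Of 7 tested, 5 fell (Skint1, Skint4, Skint7, Skint8 and Skint9) and none rose, with a median of -3.06. Skint1 went from 48.5 ± 10.4 to 7.26 ± 4.04 CPM (adjusted p = 0.004) and Skint7 from 14.6 ± 1.02 to 0.627 ± 0.490 (adjusted p = 0.00222). The neighbouring genes Clca3a1 (131 ± 29.2 to 8.55 ± 5.84 CPM) and Clca3a2 (439 ± 140 to 26.5 ± 11), which may share reads, fell by 3.94 and by 4.05 on the log2 scale, and 2 of 4 tested Clca genes fell in all.

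Ring1 did not follow the labels. A swap of the replicate-3 labels was tested on the 381 genes called between the other 4 libraries, scaled so that their control mean is 0 and their 2KO mean 1: control replicate 3 had a median position of -0.01 (quartiles -0.13 to 0.11) and 2KO replicate 3 one of 0.89 (quartiles 0.74 to 1.02), which argues against a swap and against a wrong label on either library. The spread usual at this expression level is also argued against, since 1.9% of 2213 genes of like mean CPM had a ratio among the control libraries as large as the 6.65 of Ring1. Ring1 was lower in the 3 libraries with high Xist (3.37, 1.84 and 7.34 CPM) than in the other 3 (19.5, 22.4 and 14.1 CPM), a split for which 3 against 3 libraries allow no exact p below 0.1. Differences in Ring1 genotype within the control group, and transcripts from disrupted alleles, stay open and were not tested.

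The rise of lineage transcription factors may follow from the loss of Polycomb repression that the labels name, which is a hypothesis. GC content and transcript length are argued against as the whole cause, because all 49 calls remained with their trends removed (median log2 fold change 5.46). Dermal fibroblasts mixed into the libraries labelled 2KO were predicted to raise the summed CPM of Col1a1, Col1a2, Col3a1, Dcn and Lum by more than that of the list's genes. That sum went from 557 ± 173 to 679 ± 69.4, and the sum of the list's 70 genes from 523 ± 69.4 to 1120 ± 95.3. The ratio of rises was 0.2, below the prediction but not under the bound set for excluding fibroblasts, so this test cannot tell. None of the summed fibroblast genes was among the 8 that rose, and sums say little about factors at low levels. Fibroblasts as a cause thus stay open. Of the 24 tested fibroblast genes 8 rose, and 14 were at 10 CPM or more in the control libraries already. The protocols name a stain for EpCAM, but how far the sort removed fibroblasts was not tested. For the 1351 genes past the threshold, 1 of 10 splits of the libraries, the real one, gave as many and the highest other gave 5; 10 splits are too few for a share under 0.05.

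Whether the fall of replication genes rests on control replicate 1 cannot be told by the bounds written beforehand, which asked for 10 remaining calls to exclude it, while 7 remained. Without that library the median log2 fold change of the S phase list was -1.07 (upper quartile -0.87), all 34 members stayed below 0, and the mean log2(CPM + 1) of the list was at most 4.35 in the libraries labelled 2KO and at least 5.09 in control replicates 2 and 3. These values argue against control replicate 1 alone as the source of the list's fall. The number of calls also dropped to 8 without 2KO replicate 3, so that drop was not particular to control replicate 1. Whether fewer cells were cycling, or replication genes changed within cycling cells, stays open. The difference between the S phase and mitosis lists shifted by -0.58 between the groups, with ranges of -0.6 to 0.13 in control and -0.98 to -0.5 in 2KO. These overlap through control replicate 1 alone; without it the lowest control value is -0.19, above every 2KO library. The wording of the bound for that test was changed once after its result was seen.

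Among the Hox genes the direction differed with the position in the cluster, a split chosen from these same values. A permutation test run on them can only restate it, so its p is not given. The 15 tested genes of paralog groups 9 to 13 had a median log2 fold change of 3.74 and the 21 of groups 1 to 8 one of -0.49, a difference of 4.23. Of the posterior genes 8 rose and 1 fell (Hoxc13), and of the anterior genes 0 rose and 1 fell (Hoxa2).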
